A study of Rattus norvegicus with 4 samples.

How the data were processed

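The 4 libraries were made from cultured neonatal rat cardiomyocytes, heart muscle cells taken at postnatal day 3, that had received an adenovirus vector encoding mock or Pdk3. Per the labels' protocols, total RNA was isolated with a column kit and 1 µg of it went into a stranded mRNA library. The labels give 2 libraries per group and do not say whether these came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

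The submitters' processing notes name FastQC, Trimmomatic 0.39, STAR 2.6.1d, featureCounts 1.6.5 from the Subread package, DESeq2 1.26.0 and the rat genome build rn6, with no settings. The authors deposited 1 table with 16290 genes (Ensembl identifiers, symbols and coordinates per the file headers) and 1 column per library. The deposited values are used here as a score: they are read counts per gene that the authors normalized between libraries and rounded to whole numbers, not raw counts. Totals per library differed by 0.64%, and whole numbers were skipped or doubled at regular steps, as division by a factor followed by rounding leaves. From these steps the scaling factors were estimated as 1.0255 and 1.0567 for Mock 1 and Mock 2, and as 0.9246 and 0.9627 for Pdk3 1 and Pdk3 2. Multiplied back, the values correspond to about 4562000, 4707000, 4139000 and 4304000 reads in genes. The treatment of duplicate reads, the strand setting and the gene filter are not given in the sources used here. Without the strand setting, reads of overlapping antisense genes cannot be assigned with certainty, and counts of near-identical copies such as the alpha globin genes are uncertain.

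Values were tested on the log2(value + 1) scale with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with the group as the single term. A gene entered the test with a value of at least 10 in at least 2 libraries, which kept 12838 genes, 12461 of them protein coding. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The fit had 2 residual degrees of freedom and a prior of 5.56. Errors of means are SDs over n = 2 libraries, and errors of log2 fold changes are standard errors from limma. These errors reflect counting error at this depth at best, because reads without molecular identifiers are not independent molecules.

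A total of 31 gene lists were planned for set tests before the data were examined, 7 of them primary, 17 secondary and 7 of cell type markers, and 1 more list of sex-linked transcripts served as a check of the libraries. For 1 planned list, the mitochondrial DNA-encoded transcripts, 0 genes had a value, and the other 30 were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over the lists. Alongside these stand camera with an estimated correlation, fry, and counts of members past the threshold, both over all genes tested and adjusted over the list alone. Pathway and ontology terms given in the table, with 15 to 300 tested genes, were tested with camera in the same way.

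The text names genes by a rule fixed at the same time. It takes Pdk3 and the members of the pyruvate dehydrogenase list. It also takes the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 50 in the higher group and a symbol that is not a clone or locus identifier. From each list it takes up to 4 members past the threshold in the majority direction and up to 2 in the other, by smallest p, or up to 2 members of highest mean where none passed. The rule yields 153 genes, from which examples are printed. A few genes are named outside the rule. Rsad2 was chosen after its values were seen, and Dst, Cxcl1 and Cxcl2 are named because of their values. Gapdh and Kdm5d are given for their levels only.

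The spread within each pair was compared with counting noise by a chi-square test on the values multiplied back to reads. Alternatives were a replicate block, each library left out, TMM scaling written for these values, no filter on low values, a minimum of 50, pseudocounts of 0.5 and 8, limma without a trend, a false discovery rate of 0.01 and a minimum change of 1 on the log2 scale. Chosen after seeing the data were a scaling that levels the median ribosomal protein gene, a floor at counting noise (the larger of limma's p and the exact binomial p of the summed reads), and tests with counting noise alone.

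The tests were tried on simulated data for the comparison of Pdk3 against mock over 12838 genes, drawn from the real means and scaling factors with counting noise. Changed genes were drawn from those with a mean of at least 50, and far fewer genes changed than were called in the real data. limma recovered 50% of 50 genes changed 1.25-fold, 80% of 50 changed 1.5-fold, and 100% of 50 changed 2-fold, with 2 false calls. With the simulated spread at 0.6 of counting noise, near that of the real pairs, it recovered 60%, 90% and 100% with 0 false calls. A simulated list with every member raised 1.25-fold had p = 2.29e-39 in camera at the preset correlation and p = 0.00444 with an estimated correlation, and 0 of 100 lists with no change passed an unadjusted 0.05 in either. At 0.6 of counting noise these p were 9.55e-49 and 0.00555, and 3 of 100 lists with no change passed camera at the preset correlation, 0 with an estimated correlation and 5 in fry (4 at counting noise). Simulated genes were drawn independently of each other, so lists with no change do not test the error rate for correlated genes. In the real lists the estimated correlation reached 0.312, for mitosis. The estimate of scaling factors was tested on 4 simulated columns. Plots and the remaining statistics used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No genome sequence was used here, and coordinates are those of the table.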

Results

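RNA was sequenced from cultured neonatal rat cardiomyocytes that received an adenovirus vector, a viral carrier for gene delivery, encoding mock or Pdk3. There were 2 mock libraries (Mock 1 and Mock 2) and 2 Pdk3 libraries (Pdk3 1 and Pdk3 2). Normalised read counts summed to 4448199 and 4454567 in Mock 1 and Mock 2 and to 4476649 and 4470251 in Pdk3 1 and Pdk3 2. The median gene had a normalised count of 140 to 144. The series title places the work in a study of glycolysis, the pyruvate dehydrogenase axis and cardiomyocyte proliferation, and the comparison asks how the transcriptome of these cells differs when Pdk3 is expressed. Pdk3 encodes a pyruvate dehydrogenase kinase, an enzyme that phosphorylates and inhibits the pyruvate dehydrogenase complex, which feeds pyruvate into the mitochondrial citric acid cycle.

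In the Pdk3 libraries 37 of 37 genes of DNA replication, 36 of 37 of mitosis and 28 of 30 of sterol and fatty acid synthesis rose, with median log2 fold changes of 1.16, 0.64 and 0.49. The set calls of these lists were lost with an estimated correlation (adjusted p = 0.164, 0.347 and 0.164). Of the genes of fatty acid oxidation 12 of 29 fell, of inflammatory genes 12 of 24 and of macrophage markers 7 of 16, with medians of -0.09, -0.27 and -0.33. Their set calls were lost as well (adjusted p = 0.326, 0.325 and 0.356 with an estimated correlation). The median log2 fold changes of glycolysis genes (0.067) and sarcomere genes (0.070) were close to that of ribosomal protein genes (0.076), with larger changes in single members such as Aldoc, Slc2a4, Myl4 and Myom3.

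Pdk3 itself (ENSRNOG00000012513, chromosome X, 62836131 to 62903554, minus strand, rn6) had normalised counts of 396 and 411 in the mock libraries and of 1218 and 1177 in the Pdk3 libraries. The mean rose from 403.5 ± 10.6 to 1197.5 ± 29.0 (SD, n = 2 each), a 2.96-fold rise with a log2 fold change of 1.57 ± 0.03 (limma, adjusted p = 1.47e-06). Reads of the vector and of the cells' own gene are not separated in these values. Of the other kinases of the complex, Pdk4 (ENSRNOG00000009565, chromosome 4, 30546664 to 30556814) fell from 360.0 ± 0.0 to 251.5 ± 7.8, a log2 fold change of -0.52 ± 0.05 (adjusted p = 0.000361). Pdk1 had log2 fold changes of -0.08 (adjusted p = 0.282) and Pdk2 of -0.06 (adjusted p = 0.304), neither past the threshold.

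Across the 14 members of the pyruvate dehydrogenase axis, 4 rose and 1 fell, and 4 and 1 also passed when adjusted over the list alone. Besides Pdk3 and Pdk4 these were Pdhx and Dlat, 2 subunits of the complex, and Pdp2, a phosphatase that activates it. Their rises were small, with log2 fold changes of 0.15 for Pdhx, 0.13 for Dlat and 0.35 for Pdp2. When p was floored at counting noise, their adjusted p values were 0.0737, 0.141 and 0.0622, and the calls ended. Pdha1, Pdhb and Dld and the mitochondrial pyruvate carrier genes Mpc1 and Mpc2 did not pass, with log2 fold changes between -0.04 for Mpc2 and 0.11 for Mpc1. As a set the list did not pass camera (adjusted p = 0.153, and 0.531 with an estimated correlation), and it passed fry (0.0366).

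**Figure D1:**
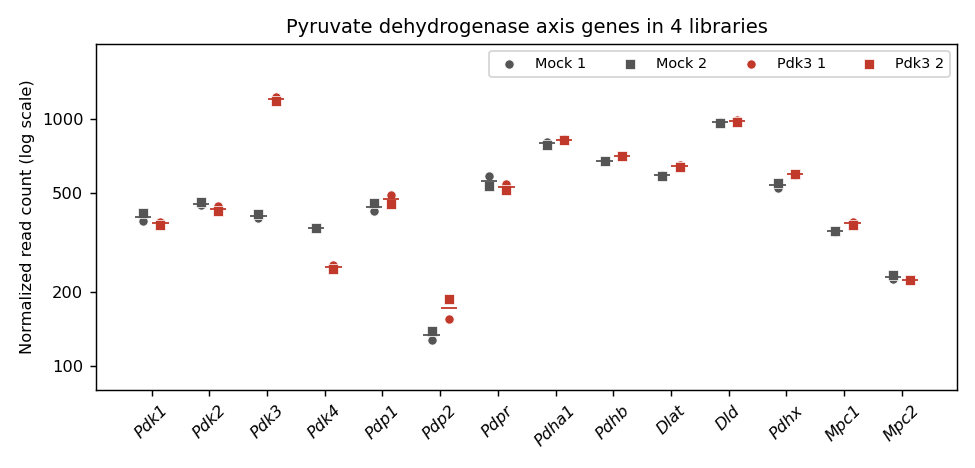
Normalised read counts (log scale) of the 14 pyruvate dehydrogenase axis genes in each of the 4 libraries, with a line at each group mean. Pdk3 stands at 1218 and 1177 in the Pdk3 libraries against 396 and 411 in mock, and Pdk4 at 257 and 246 against 360 in both mock libraries.

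Of the 12 genes with the largest rises, 3 (Clspn, Cdc6 and Dtl) are on the DNA replication list. Kif24, a kinesin, rose 5.11-fold (17 and 15 in mock, 80 and 92 with Pdk3). E2f7 and E2f8, repressors of the E2F family that act in the cell cycle, rose 4.09-fold and 3.89-fold. Clspn and Ticrr, which act at replication forks and origins, rose 4.07-fold and 4.01-fold, the licensing factor Cdc6 3.92-fold and the ubiquitin ligase adaptor Dtl 3.56-fold. Dscc1 rose 3.97-fold, Pole2, a DNA polymerase epsilon subunit, 3.74-fold, Aunip 3.80-fold, the adhesion gene Amigo2 3.92-fold and Xkr5 3.46-fold. Adjusted p of these 12 genes lay between 1.15e-05 for Cdc6 and 0.00128 for Aunip.

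Among the large falls, the chemokine genes Cxcl6 and Cxcl11 were 4.35-fold and 2.83-fold lower. Lrat, which esterifies retinol, was 3.80-fold lower, the metalloproteinase gene Mmp24 2.93-fold, Itih4 2.73-fold, Kbtbd11 2.6-fold, Klhl33 2.59-fold and Angptl4, a secreted inhibitor of lipoprotein lipase, 2.52-fold. Steap4, the adhesion receptor gene Selp and the lipase gene Lipe were 2.48-fold, 2.41-fold and 2.26-fold lower. Kbtbd11 had counts of 31 and 14 in the Pdk3 libraries and an adjusted p of 0.0218.

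Over all 12838 genes tested, 1496 were higher and 1449 lower in the Pdk3 libraries, 22.9% of the genes tested. Most changes were small, with a median log2 fold change of 0.30 among the higher and -0.26 among the lower genes. With a minimum change of 1 on the log2 scale, 157 genes were higher and 51 lower. Scaled so that the median ribosomal protein gene was level, an alternative chosen after seeing the data, the split was 929 higher to 3570 lower (20.6% higher, against 50.8%), with the median gene at -0.09 in place of -0.01. With p floored at counting noise, 1064 genes were higher and 946 lower. With any 1 library left out, limma called 0 genes in either direction with 1 residual degree of freedom, while 2916 to 3347 genes had an unadjusted p under 0.05 and tests with counting noise alone called 770 to 831 higher and 595 to 724 lower. Of the 142 named genes past the threshold, calls ended for 27 with the floor at counting noise, 77 without an intensity trend and 50 without a filter on low values.

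**Figure D2:**
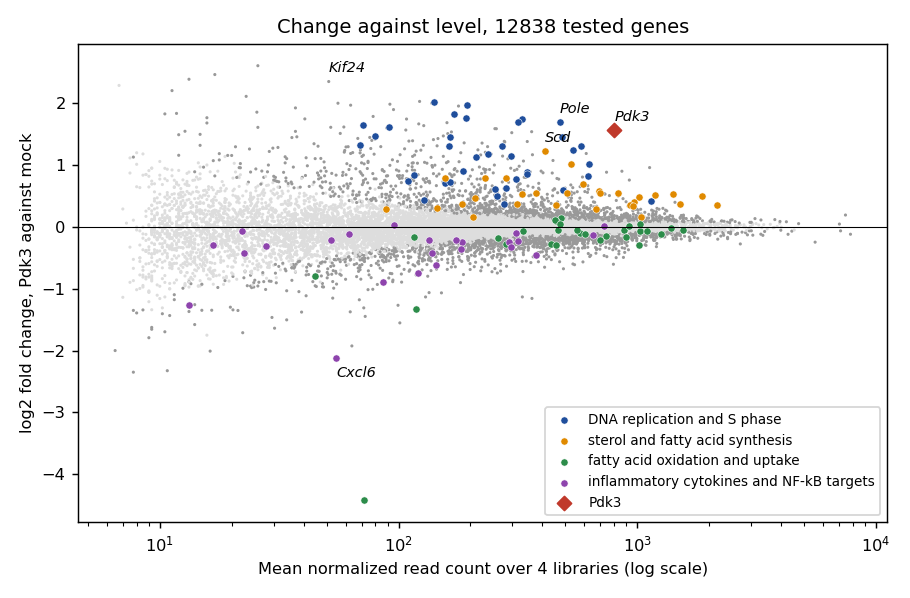
log2 fold change of Pdk3 against mock (vertical axis) against the mean normalised read count over the 4 libraries (log scale) for the 12838 genes tested, with dark grey points past the threshold and members of 4 lists in colour. The DNA replication genes lie above 0, with a median of 1.16, and Cxcl6 lies at -2.12.

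Every one of the 37 measured genes of DNA replication and S phase rose, and 37 passed when adjusted over the list alone. Their median log2 fold change was 1.16, or 2.23-fold, with a range of 0.37 to 2.03. Pole, the catalytic subunit of DNA polymerase epsilon, rose from 223.0 ± 2.8 to 726.0 ± 7.1 (3.25-fold, adjusted p = 1.47e-06). The helicase subunits Mcm5, Mcm6 and Mcm2 rose 2.76-fold, 2.47-fold and 2.02-fold. As a set the list was higher than other genes (camera adjusted p = 2.29e-37). With an estimated correlation, of 0.014, the list did not pass after adjustment (camera p = 0.00644, adjusted p = 0.164). Floored at counting noise, 37 of its members still passed.

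Genes of mitosis and cytokinesis rose as well, though by less, with 36 of 37 measured members past the threshold and a median of 0.64 (1.56-fold). Adjusted over the list alone, 37 rose. The proliferation marker Mki67 rose from 772 and 755 to 1460 and 1517 (1.95-fold, adjusted p = 3.05e-06). Top2a, the topoisomerase that untangles chromosomes, rose 1.87-fold, the spindle kinesin Kif11 1.84-fold and the centromere protein gene Cenpf 1.59-fold. Camera gave an adjusted p of 1.52e-27 for the list and, with an estimated correlation, an adjusted p of 0.347.

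Among 25 measured G1 cyclins, kinases and cell cycle inhibitors, 7 rose and 4 fell, and 8 rose and 4 fell adjusted over the list alone. Floored at counting noise, 5 rose and 0 fell. Wee1, an inhibitory kinase of the cell cycle, rose 1.47-fold, the pocket protein gene Rbl1 1.92-fold, Cdk2 1.42-fold and Pkmyt1 2.06-fold. The inhibitor Cdkn1b had a log2 fold change of -0.18 (adjusted p = 0.0149) and Btg2 of -0.13 (adjusted p = 0.0226), both lost when floored at counting noise (adjusted p = 0.0817 and 0.0525). The list did not pass camera as a set (adjusted p = 0.301) and passed fry (0.0128).

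Genes of sterol and fatty acid synthesis rose together, 28 of 30 measured members past the threshold, none of them falling, and 29 adjusted over the list alone. Their median log2 fold change was 0.49 (1.41-fold). The desaturase genes Scd and Fads1 rose 2.35-fold (245.0 ± 11.3 to 576.0 ± 21.2) and 2.02-fold. Scd2 rose 1.42-fold (1544.5 ± 0.7 to 2188.0 ± 17.0). The set test gave an adjusted p of 4.84e-26, and an adjusted p of 0.164 with an estimated correlation.

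Genes of fatty acid oxidation and uptake moved the other way, with 12 of 29 measured members lower and 1 higher (13 and 2 adjusted over the list alone). Besides Angptl4, Cpt1a, which admits long-chain fatty acids to mitochondria, fell from 1121.0 ± 22.6 to 919.5 ± 9.2 (log2 fold change -0.29 ± 0.03), and Mlycd, which degrades malonyl-CoA, fell from 477.0 ± 2.8 to 395.5 ± 2.1. The member that rose was the coactivator Ppargc1a, with a log2 fold change of 0.15 (adjusted p = 0.0205, and 0.108 floored at counting noise). The median of the list was -0.09 and its mean -0.30. The set was lower by camera (adjusted p = 0.000206), with an adjusted p of 0.326 with an estimated correlation.

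Glycolysis genes showed small rises. Of 23 measured members, 6 rose and 1 fell (8 and 1 adjusted over the list alone), and the median log2 fold change was 0.07. The glucose transporter genes Slc2a4 and Slc2a1 rose 1.31-fold (262.5 ± 9.2 to 343.5 ± 3.5) and 1.15-fold. The lactate transporter gene Slc16a3 rose 1.14-fold and Pfkl, a phosphofructokinase, 1.11-fold. Aldoc, an aldolase, fell from 505 and 495 to 314 and 322 (log2 fold change -0.65 ± 0.04, adjusted p = 5.59e-05). The set test gave an adjusted p of 0.00456, and an adjusted p of 0.347 with an estimated correlation.

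Respiratory genes encoded in the nucleus had 3 of 48 members past the threshold, all higher, and 0 adjusted over the list alone. These were Atp5f1a and Atp5f1b of ATP synthase (log2 fold change 0.09 each, that of Atp5f1b turning sign when scaled to ribosomal protein genes) and Cox4i1 of cytochrome c oxidase (0.13), and 0 of them passed when floored at counting noise. The list's median was 0.05 (camera adjusted p = 0.0164, 0.531 with an estimated correlation, and 0.0846 floored at counting noise, and 0.0567 with a minimum value of 50). In the citric acid cycle list, Mdh1 rose by 0.17 and Dlst by 0.09 on the log2 scale among 17 measured members (Dlst with an adjusted p of 0.128 floored at counting noise, and with its sign turned when scaled to ribosomal protein genes). Adjusted over the list alone, 1 rose, Mdh1. Mdh1 encodes the cytosolic malate dehydrogenase, not the enzyme of the cycle. Mdh2, the mitochondrial enzyme of the cycle, had a log2 fold change of 0.02 (limma adjusted p = 0.628). That list gave an adjusted p of 0.0411, an adjusted p of 0.347 with an estimated correlation, 0.114 floored at counting noise, 0.0977 with a minimum value of 50 and 0.122 without an intensity trend, and without Pdk3 1 it gave 0.0513. Transcripts of mitochondrial DNA were not analysed here.

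Ribosomal protein genes, which are on none of these lists, stood a little higher in the Pdk3 libraries too. Their median log2 fold change was 0.076 ± 0.013 (SE) over 68 genes, 58 of them above 0 and 0 past the threshold. That is close to the medians of glycolysis (0.067), oxidative phosphorylation (0.045) and the sarcomere (0.070). With the median ribosomal protein gene set level, camera gave these lists adjusted p of 0.284, 0.530 and 0.727, with medians of -0.020, -0.041 and -0.017 and the test still upward against other genes. That scaling lowers all genes by nearly the same log2 amount. The median gene went from -0.007 to -0.093, and the calcium handling median from -0.02 to -0.106. Calls gained or lost there therefore do not show that a list moved against other genes. Under that scaling the citric acid cycle list turned downward (0.852), the lists of fetal genes (0.230), ribosome biogenesis (0.0785) and erythroid markers (0.230) no longer passed, and calcium handling (0.0328), the unfolded protein response (0.0109), YAP targets (0.0261) and matrix genes (0.0277) passed downward. The balance of higher to lower members turned as well for the pyruvate dehydrogenase axis (1 to 4), the citric acid cycle (0 to 2), oxidative phosphorylation (0 to 2), G1 cyclins and inhibitors (5 to 9), fetal genes (3 to 5), HIF targets (3 to 7) and matrix genes (0 to 11), and it was 3 to 3 for glycolysis and 2 to 8 for interferon-stimulated genes. Over all genes tested the balance was 929 to 3570, so such turns go with the shift of all genes. The calls of Pdhx, Dlat, Pdp2, Pfkl, Mdh1, Atp5f1a, Cox4i1, Ppargc1a, Myh7, Myh6, Casq2, Hcn2, Egln3, Dnajb11, Nt5e, Ncl, Nolc1 and Sparc ended there, and Pdk1, Pdk2, Pdpr and Erbb3 passed with negative values.

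Of 30 measured sarcomere genes, 11 rose and 3 fell (16 and 3 adjusted over the list alone, 6 and 3 floored at counting noise). Scaled to ribosomal protein genes, which lowers all genes nearly alike, 2 rose and 7 fell. Myl4, the atrial light chain, rose 1.33-fold, the actin-binding repeat gene Xirp2 1.14-fold (6944.5 ± 116.7 to 7946.5 ± 194.5), and the myosin heavy chain genes Myh7 and Myh6 by 0.12 and 0.09 on the log2 scale. The M-band gene Myom3 fell by 1.01 on the log2 scale. The set passed camera (adjusted p = 0.000995), with an adjusted p of 0.347 with an estimated correlation. Fetal and stress genes of cardiomyocytes had 8 of 20 higher and 1 lower (9 and 1 adjusted over the list alone, 5 and 0 floored at counting noise). Among the higher were the transcription factor gene Mef2c (1.24-fold), the skeletal actin gene Acta1 (1.21-fold) and Acta2 (1.17-fold). Kit was the lower one (log2 fold change -0.14, adjusted p = 0.0334, and 0.168 floored at counting noise). Their set test gave an adjusted p of 0.0190 and, with an estimated correlation, of 0.448. Without Mock 2 it gave 0.138, without an intensity trend 0.0763 and by fry 0.0520.

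Of 26 calcium handling and conduction genes, 4 were higher and 6 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.434). Scaled to ribosomal protein genes, 0 were higher and 15 lower, against 929 higher and 3570 lower over all genes tested. The connexin gene Gja5 fell by 0.28 and the potassium channel gene Kcnj3 by 0.44 on the log2 scale. Ryr2, the calcium release channel, fell by 0.06. Casq2, which stores calcium in the sarcoplasmic reticulum, rose 1.11-fold and the pacemaker channel gene Hcn2 1.18-fold.

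In the list of the integrated stress response and serine synthesis, 11 of 25 measured members rose and 1 fell (11 and 2 adjusted over the list alone). The mitochondrial folate enzymes Mthfd1l and Mthfd2 rose 1.96-fold and 1.91-fold, and the amino acid transporters Slc7a1 and Slc7a5 1.45-fold and 1.29-fold. Ddit3, a transcription factor of the same response, fell by 0.31 on the log2 scale. The median was 0.12 and the set test gave an adjusted p of 0.00382 (adjusted p = 0.347 with an estimated correlation). Among pentose phosphate and nucleotide synthesis genes, 10 of 25 rose and 1 fell, with 10 and 1 adjusted over the list alone. Floored at counting noise, 5 rose and 0 fell. Dhodh and Umps of pyrimidine synthesis rose by 0.51 and 0.33 on the log2 scale, the folate enzyme Mthfd1 1.38-fold and Ppat, which opens purine synthesis, 1.16-fold. Impdh1 was the lower one (log2 fold change -0.15, adjusted p = 0.0480, and 0.238 floored at counting noise). That set gave an adjusted p of 0.00177, and an adjusted p of 0.347 with an estimated correlation.

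Ribosome biogenesis genes had 5 of 22 higher and 0 lower, with the same counts adjusted over the list alone, among them Nop56 (1.22-fold), Utp20 (1.19-fold), Ncl (1.11-fold) and Nolc1 (1.1-fold). The set gave an adjusted p of 0.00637, and of 0.347 with an estimated correlation. The unfolded protein response of the endoplasmic reticulum had 2 of 18 higher and 5 lower (3 and 9 adjusted over the list alone), with falls of 0.20 for the chaperone gene Hyou1, 0.20 for Sel1l and 0.22 for Herpud1 on the log2 scale and a rise of 0.17 for Dnajb11. That set did not pass (adjusted p = 0.0983).

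Of 22 immediate early genes, 1 was higher and 5 were lower, also adjusted over the list alone, and the median was -0.16 (camera adjusted p = 0.00840, and adjusted p = 0.347 with an estimated correlation). The transcription factor genes Egr1 and Junb fell by 0.37 and 0.39 on the log2 scale and the phosphatase gene Dusp1 by 0.24. Nr4a3 had a log2 fold change of 0.52 (adjusted p = 0.0450, and 0.0589 floored at counting noise). The p53 targets had 1 of 18 higher and 5 lower (2 and 6 adjusted over the list alone, 0 and 1 floored at counting noise). Tp53inp1, the 1 still lower with that floor, had a log2 fold change of -0.22. The p53 set did not pass camera (adjusted p = 0.208, and 0.0366 by fry). YAP targets had 2 of 19 higher and 4 lower (3 and 8 adjusted over the list alone), including Nuak2 (-0.55), Ajuba (-0.22) and Dock5 (0.25), with an adjusted p of 0.0997, and of 0.0305 by fry. HIF targets had 5 of 26 higher and 3 lower (5 and 5 adjusted over the list alone), including Ak4 (0.83), P4ha1 (0.28), Mxi1 (-0.40) and Bhlhe40 (-0.27), with an adjusted p of 0.543.

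Inflammatory cytokines and NF-kB targets were lower, with 12 of 24 measured members past the threshold, 13 adjusted over the list alone, and 0 higher. Besides Cxcl6, the cytokine gene Lif fell from 112 and 113 to 61 and 59, the complement gene C3 from 174 and 173 to 122 and 105, and Nfkb2, an NF-kB subunit, from 437.5 ± 4.9 to 319.0 ± 1.4. The median log2 fold change was -0.27 (camera adjusted p = 8.16e-06, and adjusted p = 0.325 with an estimated correlation). Macrophage and leukocyte markers fell alongside, 7 of 16 past the threshold, 7 adjusted over the list alone and 0 higher, with a median of -0.33. C1qa, a complement gene of macrophages, fell by 0.65 on the log2 scale, Laptm5 by 0.35, Csf1r, the receptor for macrophage growth factor, by 0.31 and Cd68 by 0.29. The marker set had an adjusted p of 0.000206, and of 0.356 with an estimated correlation. Interferon-stimulated genes had 2 of 34 higher and 2 lower (1 and 2 adjusted over the list alone) and did not pass as a set (adjusted p = 0.435). Psmb9 was at a log2 fold change of 0.70 and Parp14 at -0.23.

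Markers of other cell types moved less uniformly. Endothelial markers had 3 of 12 lower and 0 higher (4 lower and 1 higher adjusted over the list alone), with falls of 0.52 for Cdh5, the endothelial cadherin, and 0.39 for Tie1, and the set did not pass (adjusted p = 0.0693), though it did without Mock 1 (0.0307), without an intensity trend (0.0152), without a filter on low values (0.0448) and by fry (0.0269). Smooth muscle and pericyte markers had 4 of 13 higher and 1 lower, also adjusted over the list alone, including Cnn1 (1.27-fold), Tagln (1.19-fold) and Cspg4 (1.14-fold), with Abcc9 lower by 0.13 on the log2 scale. Their median was -0.001 and their mean 0.058, and the set test (upward) gave an adjusted p of 0.162. Among 14 fibroblast markers, Dcn, a matrix proteoglycan gene, was lower (-0.31) and 0 were higher, with 1 and 0 adjusted over the list alone (adjusted p = 0.513). Matrix and transforming growth factor targets had 2 of 25 higher, Sparc (0.09) and Col4a2 (0.08, turning sign when scaled to ribosomal protein genes), and 1 lower, Tgfb1 (-0.18), with 0 adjusted over the list alone and 0 with the floor at counting noise (adjusted p = 0.656). Epicardial and mesothelial markers had 2 of 10 lower, Krt19 (-0.97) and Lrrn4 (-0.75), with 2 adjusted over the list alone (camera adjusted p = 0.435, and 0.0242 by fry). Of the Schwann and neural crest markers 2 were measured, among them Erbb3 with counts of 41, 31, 16 and 24 (adjusted p = 0.309 for the pair, and 1 lower adjusted over the list alone). Erythroid markers had 3 members that entered the test, 2 of them copies of Hba-a2 at low counts of 6 to 24, both lower (adjusted p = 0.0411, and 0.347 with an estimated correlation, and 2 adjusted over the list alone). Sex-linked transcripts were present in every library, with Kdm5d, on the Y chromosome, at 351, 373, 333 and 337.

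**Figure D3:**
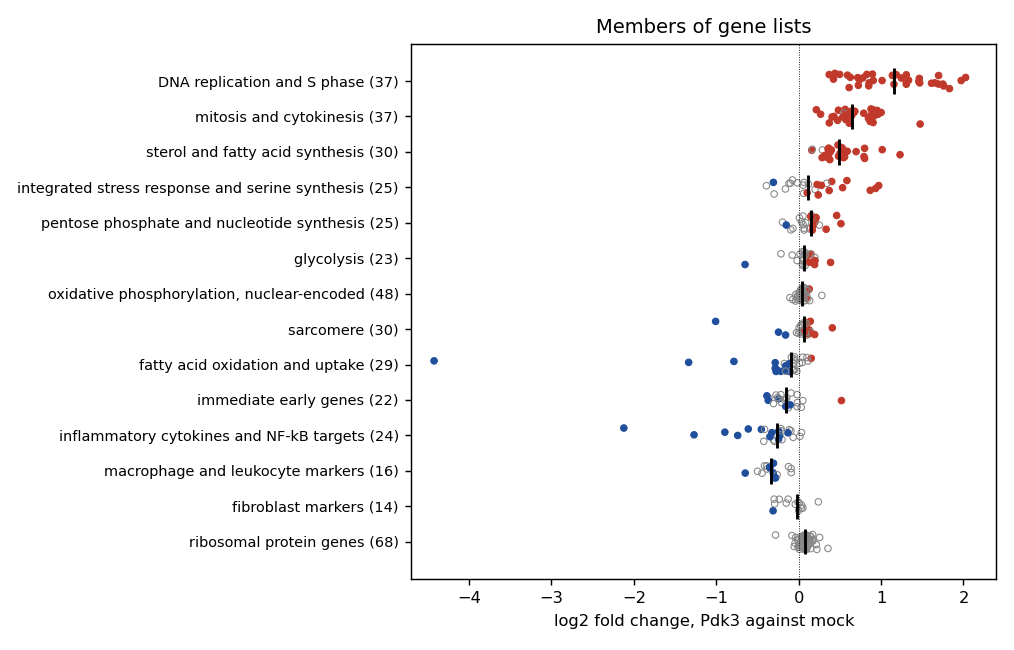
log2 fold changes of Pdk3 against mock for the measured members of 13 gene lists and of 68 ribosomal protein genes, with the number of genes in parentheses, a black line at each median, filled points past the threshold (red higher, blue lower) and open points not past it. The replication list has a median of 1.16, the mitosis list 0.64 and the sterol and fatty acid synthesis list 0.49, while the medians of glycolysis and the ribosomal protein genes are 0.067 and 0.076.

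The libraries of each pair lay closer together than counting noise allows. The variance between Mock 1 and Mock 2 was 0.601 times the counting variance over 12838 genes, and between Pdk3 1 and Pdk3 2 it was 0.606 times, against 3.27 to 3.56 times between a mock and a Pdk3 library. In genes with a mean of 10 to 50 the ratio was 0.822 in the mock pair and 0.867 in the Pdk3 pair, and at 800 or more it was 0.429 and 0.451. The 10 most abundant genes held at most 1.3% of the counts, led by the long genes Dst, Xirp2 and Ryr2, while Gapdh stood at 312 to 333. Interferon-stimulated genes did differ within the mock pair (2.523 times the counting variance, chi-square p = 2.31e-06), with Rsad2, chosen after its values were seen, at 59 and 23. In the Pdk3 pair no list exceeded counting noise after adjustment (highest 1.312, HIF targets, chi-square p = 0.132). Libraries are treated as n = 2 per group, as the labels give them.

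**Figure D4:**
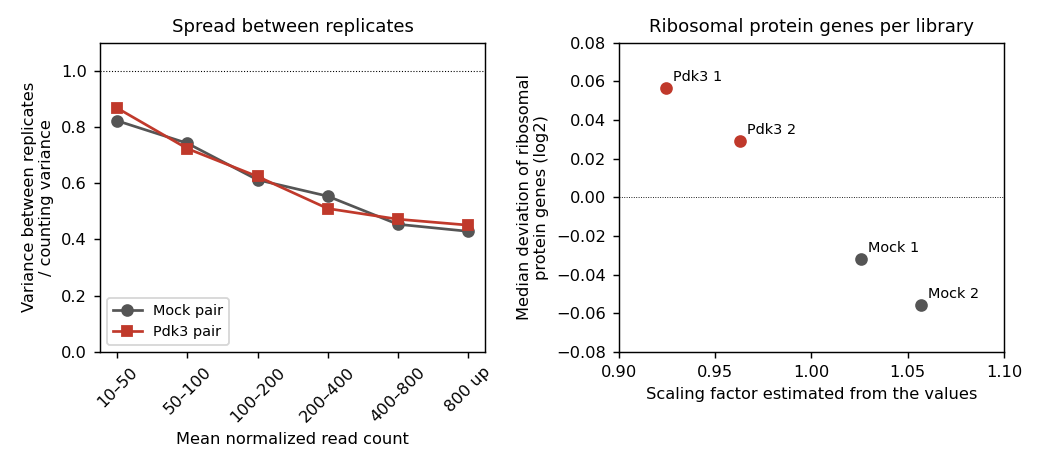
Left, variance between the 2 libraries of a pair divided by the counting variance, by mean normalised read count, with a dotted line at 1. Right, median deviation of 68 ribosomal protein genes (log2) in each library against the scaling factor estimated from the values, from -0.056 in Mock 2 to 0.057 in Pdk3 1.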

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

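The scaling to ribosomal protein genes, the floor at counting noise and the tests with counting noise alone were chosen after seeing the data. TMM scaling, a minimum of 50, pseudocounts of 0.5 and 8 and each pair summed as 1 library kept both counts of genes within 1.5 times of 1496 higher and 1449 lower. Without a filter on low values 737 were higher and 539 lower, without an intensity trend 526 and 325, at a false discovery rate of 0.01 766 and 576, with a minimum change of 1 on the log2 scale 157 and 51, and scaled to ribosomal protein genes 929 and 3570. With the floor at counting noise 946 were lower. The stricter thresholds call fewer genes by construction, and for the others the cause was not tested. With 1 library left out, limma called 0 genes higher and 0 lower in each case (1 residual degree of freedom, with the lone library assumed to vary like the other group), while 2916 to 3347 genes had an unadjusted p under 0.05. Counting noise alone called 770 higher and 620 lower without Mock 1, 831 and 724 without Mock 2, 788 and 622 without Pdk3 1, and 771 and 595 without Pdk3 2.

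Same-numbered libraries deviated with r = 0.038 across genes (Spearman 0.018), and with 2 pairs and no pairing in the labels the numbers were not taken as pairs. With a replicate block 1374 genes were higher and 1298 lower, and the log2 fold change of the Pdk3 transcript was 1.57. The Pdk3 transcript lay between 1.54 and 1.59 with each library left out, at adjusted p of 0.149 to 0.173, and passed under the other settings run. Of 153 named genes, 0 changed sign with a library left out and 27 lost their call with the floor at counting noise.

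With an estimated correlation none of the 16 lists called by camera passed (adjusted p = 0.164 for DNA replication and S phase, 0.326 for fatty acid oxidation, 0.347 for glycolysis, mitosis and the sarcomere, and 0.531 for oxidative phosphorylation), though 4 lists had an unadjusted p under 0.05. That test has little power with 2 residual degrees of freedom, so a lost call does not decide whether a list moved. The estimated correlation was 0.014 for DNA replication, 0.023 for sterol and fatty acid synthesis and -0.023 for fatty acid oxidation, but 0.312 for mitosis. fry, which does not compare a list with other genes, called 6 more lists than camera, the pyruvate dehydrogenase axis (adjusted p = 0.0366), G1 cyclins and inhibitors (0.0128), p53 targets (0.0366), YAP targets (0.0305), endothelial markers (0.0269) and epicardial markers (0.0242), and lost fetal genes (0.0520) and oxidative phosphorylation (0.123), which was also lost with a minimum of 50 (0.0567) and the floor at counting noise (0.0846). Scaled to ribosomal protein genes, glycolysis (0.284), oxidative phosphorylation (0.530) and the sarcomere (0.727) lost their calls, with medians below 0 and the test still upward against other genes. That scaling lowers all genes nearly alike, so a list's median keeps nearly the same distance from the median gene. The citric acid cycle list turned downward (adjusted p = 0.852), and the log2 fold changes of Dlst (-0.00044), Atp5f1b (-0.00102), Canx (-0.00433), Ccng1 (-0.01623) and Col4a2 (-0.01097) changed sign. With each library left out, the lists of replication, mitosis, fatty acid oxidation, glycolysis, oxidative phosphorylation and the sarcomere passed each time, the citric acid cycle list ranged from 0.0224 to 0.0513, that of fetal genes from 0.0143 to 0.138 and endothelial markers from 0.0307 to 0.0903. Endothelial markers also passed without an intensity trend (0.0152) and without a filter on low values (0.0448), while without a trend the lists of the citric acid cycle (0.122) and fetal genes (0.0763) did not. Depth limits small changes: in simulated data the smallest changes tried were recovered for 50% of genes at counting noise and 60% at 0.6 of it. These shares are not detection rates for the real data, where many more genes were called. They also leave out genes with a mean under 50. Among the real calls, 459 higher and 486 lower genes changed by less than 0.2 on the log2 scale.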

Other observations

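The annotation in the table was tested as terms, a test chosen in advance. Genes of the fixed lists were not removed from the terms, and the overlap was not counted. Terms of repair and of fatty acid degradation are therefore not findings separate from the replication and fatty acid oxidation lists. Of 257 pathway terms 17 were higher and 18 lower, and of 4172 ontology terms 183 were higher and 94 lower. None passed with an estimated correlation, a test with little power here (lowest adjusted p = 0.729 and 0.785). Repair pathways were higher: mismatch repair had 17 of 22 genes up and 0 down (adjusted p = 7.58e-10), the Fanconi anemia pathway, which repairs DNA crosslinks, 23 of 46 up and 4 down (adjusted p = 2.31e-06), and homologous recombination 15 of 26 up and 1 down (adjusted p = 4.64e-05). Aminoacyl-tRNA biosynthesis, which charges tRNAs with amino acids, had 16 of 42 up and 2 down (adjusted p = 0.0102), and RNA transport 37 of 139 up and 4 down (adjusted p = 0.00015). Complement and coagulation cascades had 12 of 40 genes down and 2 up (adjusted p = 0.00015), and the lysosome, the organelle that degrades cell contents, 18 of 103 down and 2 up (adjusted p = 0.0114). Fatty acid degradation had 9 of 31 down and 2 up (adjusted p = 0.0149).

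The tests in the rest of this part were chosen after the results they bear on were seen. The replication list rose more than the mitosis list, by 0.457 in mean log2 fold change (permutation p = 1e-05, the smallest that 100000 permutations can give, across genes, which are not independent replicates), at similar mean counts of 294 and 306. A hypothesis that the falls of Angptl4, Cpt1a and other fatty acid genes belong to a wider fall of PPAR targets was not borne out by the pathway term for PPAR signaling: 15 of its 49 genes fell and 6 rose, and the term did not pass (adjusted p = 0.195).

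The small rises of lists of abundant genes and the close agreement of replicates may share a technical source, a ceiling on counts per gene such as removal of reads with the same position leaves, combined with fewer reads in the Pdk3 libraries. Ribosomal protein genes rose by a median of 0.076 ± 0.013, and within each pair they were higher in the library with the smaller scaling factor, though within about 2 SE of 0 (0.028 ± 0.017 and 0.027 ± 0.017), and the spread between replicates fell to at most 0.451 of counting variance in abundant genes from at least 0.822 in low ones. The means of the lists minus that of the ribosomal protein genes were -0.024 for glycolysis (permutation p = 0.418), -0.028 for oxidative phosphorylation (p = 0.051) and -0.046 for the sarcomere (p = 0.145). The rises of these lists were thus no larger than that of the ribosomal protein genes. Against all other genes, camera at the preset correlation called these lists higher (adjusted p = 0.00456, 0.0164 and 0.000995). A true rise of ribosomal protein genes with Pdk3 is not excluded. That both mock numbers come from 1 library is argued against by the interferon-stimulated genes, at 2.523 times counting variance (adjusted chi-square p = 6.7e-05 over 29 lists). For the Pdk3 pair 1 library under both numbers cannot be told apart from separate ones, since the list with the largest spread, HIF targets, reached 1.312 times counting variance (chi-square p = 0.132).

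The rise of the replication and mitosis lists was 0.837 larger in mean log2 fold change than that of the ribosomal protein genes (permutation p = 1e-05, the smallest possible), which argues against such a ceiling as its only source. A larger share of fibroblasts or smooth muscle cells is argued against by their 27 measured markers, at a mean of -0.013 ± 0.034 (SE) and at most 0.348, against 0.643 for the median mitosis gene. An effect of Pdk3 on cycling in the cultured cells stays open as a hypothesis, and so does which cells cycled, since other cells in the culture could also enter the cycle and these values do not separate cell types.

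The fall of macrophage markers is consistent with fewer macrophages in the Pdk3 cultures: the 16 markers fell by a common log2 fold change of -0.28 ± 0.03, all 16 below 0, with a spread around it within counting noise (chi-square heterogeneity p = 0.395, a test with little power here, since replicates spread by less than counting noise). Csf1r and Laptm5 had mean counts of 300.5 and 334.0 in mock, and lower expression by the same number of cells stays open, as it was not tested. For the inflammatory and NF-kB list the share of macrophages alone is argued against, since 6 of 24 members, C3, Cxcl1, Cxcl2, Cxcl6, Lif and Nfkb2, lay below the common value by more than 2 counting SE against 0.55 expected by chance (binomial p = 1.31e-05). The binomial p takes genes as independent, which they are not. Cxcl6 (-2.12) and Lif (-0.90) fell further than the macrophage marker C1qa (-0.65), while C3 (-0.61) and Nfkb2 (-0.45) did not. A response of other cells to Pdk3 stays open for these 6 genes.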
